A study of Mus musculus with 32 samples.

How the data were processed

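RNA-seq was performed on mouse embryonic stem cells (ESC) of strain 129S5/SvEvBrd whose Smarce1 gene carries a tag named MD, or the same tag with the substitution R42A. Smarce1 encodes BAF57, a subunit of the SWI/SNF (BAF) chromatin remodelling complexes. MD is read here as the mitotic degron, a piece of cyclin B1 that sends a protein for destruction as cells leave mitosis, and R42A as its inactive form. This reading comes from general knowledge, since the labels do not spell it out. Total RNA was taken with TRIzol and libraries were made with the KAPA Hyper Prep kit, per the labels' protocols. ESC were grown with LIF and serum on gelatin, and neural cultures were kept for 6 days in a medium that the labels name RHA-B.

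The 32 libraries cover 8 ESC clones and 4 neural clone labels. ESC of the R42A clones A04 and A10 and of the MD clones 09 and 30 form a first library series, and ESC of the R42A clones A01 and A02 and the MD clones 45 and 47 a second, with 3 libraries per clone. The neural libraries carry the labels A04, A10, 09 and 30, with 2 libraries each. The series were read from runs of consecutive library numbers in the labels. All neural libraries belong to 1 further run, so stage and library series cannot be told apart. Numbered libraries of a clone were taken as repeat cultures of it, and the clone as the replicate.

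The deposited values are expected counts per gene, 1 table per library, not normalised, in which between 1.46% and 1.70% of genes were not whole (tolerance 1e-06). The submitters' processing notes name Trim Galore 0.60, STAR 2.7.1a, RSEM 1.3.0 and DESeq2 with no version, and the build mm10, without giving their roles. Each table has 55665 entries, of which 92 are ERCC spike-in sequences with a total count of 0, which were left out. Of the 55573 genes, 55480 were matched by identifier to a position in the GENCODE M21 annotation of mm10. The submitters' notes do not state the annotation release or whether counting used strand, so overlapping and antisense genes are uncertain. Total counts per library ran from 43278459 to 96424443 (median 57874775) in 12 R42A ESC libraries and from 38699952 to 87242402 (median 54543402) in 12 MD ESC libraries. They ran from 51736118 to 62236199 (median 55011966) in 4 R42A neural libraries and from 44426448 to 62803925 (median 61548563) in 4 MD neural libraries.

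Expected counts were rounded to whole numbers and summed over the libraries of each clone. The tests were quasi-likelihood F-tests in edgeR 4.0.16 (R 4.3.3) with robust dispersion, TMM scaling, filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called changed. The ESC comparison used the 8 clone sums with library series as covariate. The neural comparison, the comparisons of neural cells with ESC in each genotype, and the difference of the MD effect between stages came from 1 fit of 4 groups on 8 sums, 4 in ESC and 4 in neural cells, of the 4 shared clone labels. Fold changes are MD against R42A, or neural cells against ESC, on the log2 scale with their standard error (SE). Levels are CPM, scaled by the TMM library size, with the SD over clones. The term MD effect stands for the difference between MD and R42A clones, whatever its cause. A p-value measures the spread between the clone sums, which includes that between libraries of a clone. Between libraries of different MD ESC clones the median absolute log2 ratio had a median of 0.137 in the first series and 0.127 in the second. Within a clone it was 0.133 and 0.104. In R42A these were 0.217 and 0.130, against 0.149 and 0.0944. The correlation within a clone in limma voom was 0.225 in ESC, so the p-values do not measure differences between clones alone. Where a group had a total count of 0, the fold was computed against 3 counts over the group and written as "at least". Such floors cover counting error only.

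The 34 gene lists were fixed before the data were examined, as were the tests and the rule for naming genes. They cover SWI/SNF subunits; naive and formative pluripotency; neural progenitors, neurons, glia, forebrain, midbrain with hindbrain, and Hox genes; mesoderm, endoderm, trophectoderm, neural crest, surface ectoderm, fibroblasts with mesenchyme, and endothelium with blood; and 2-cell-like and germline genes. The others are G1/S and G2/M genes, p53 targets, immediate early and stress genes, Nodal/TGFb/BMP, FGF/ERK, Wnt, Notch and Hedgehog responses, cholesterol synthesis, hypoxia with glycolysis, interferon response, imprinted genes, Y-linked genes, replication histones and mitochondrially encoded genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Each list was also tested with an estimated correlation, and with fry. The estimated correlation passed 0 lists in every comparison, so not passing it does not tell real shifts of lists from false ones. The preset correlation passed 3 to 14 lists when the ESC clones were split with 2 clones of each genotype in either group. Passing it in ESC therefore does not tell them apart either.

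The rule for naming took Smarce1, Pou5f1, Sox2, Nanog, Sox1, Pax6, Nes and Tubb3 in set comparisons. It added the 10 protein-coding genes per direction with the largest changes (5 in the stage comparisons) among those changed, with a mean log2 CPM of at least 1 and no overlap between clones, and up to 4 changed members per list by smallest p. It admits 715 gene results. The genes named here are a part of these, chosen after their values were seen, and some other genes are not reported here. Chromosome medians were taken over protein-coding genes with a mean log2 CPM of at least 4, as each clone's deviation from the mean of all clones of its series.

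The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a stricter filter of 1 CPM, protein-coding genes only, libraries as replicates without and with the replicate number as block, limma voom with the clone as random block, and a test against a fold of 1.5. Others were each clone left out, no series term, each ESC series alone, all clone sums in 1 fit, the neural clone sums alone, and the clone as block across stages. Scaling each chromosome separately, leaving out chromosomes 8, 11 and Y, and the replicate block with 2 numbers of the ESC clone A04 exchanged were added after seeing the data, as were 6 further gene lists.

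The steps were tested on simulated counts drawn from the real means with 200 genes changed. That is far fewer than the 7862 genes called in ESC and 8030 in neural cells. The shares recovered and false in the simulation are therefore not those of the real comparisons. For ESC, edgeR on 21293 genes recovered 18 of 67 genes at a fold of 1.5, 41 of 67 at a fold of 2 and 59 of 66 at a fold of 4, and 7.81% of its calls were false. For neural cells, on 23465 genes, it recovered 19 of 67, 26 of 67 and 42 of 66 at these folds, with 13.9% of calls false. For the difference between stages, on 23465 genes, it recovered 5 of 67, 19 of 67 and 34 of 66, with 14.7% false. These shares exceed the 0.05 threshold. For the stage comparison in R42A, 49 of 66 genes at a fold of 4 were recovered and 9.80% of calls were false, and in MD 49 of 66 and 9.52%. DESeq2 in ESC recovered 26 of 67, 49 of 67 and 59 of 66, with 34.6% false.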

Results

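RNA was measured in 32 libraries of mouse cells in which Smarce1, the gene of the SWI/SNF subunit BAF57, carries the MD tag or its R42A form. In ESC there were 4 MD clones and 4 R42A clones with 3 libraries each, and after 6 days in neural medium 2 clone labels of each genotype with 2 libraries each. Total counts per library ran from 38699952 to 96424443.

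Smarce1 RNA (ENSMUSG00000037935.16, chromosome 11, 99209047 to 99231017 in mm10) was present at similar levels in both ESC genotypes, at 114 ± 5.53 CPM in MD and 107 ± 12.9 CPM in R42A (SD, n = 4 clones). The log2 change was 0.09 ± 0.09 (SE) with an adjusted p of 0.438 in edgeR. On the log2 CPM scale the R42A clones lay at 7.01, 6.69, 6.80 and 6.58 and the MD clones at 6.81, 6.81, 6.97 and 6.87. In neural cells Smarce1 RNA was higher in MD, at 293 ± 7.20 CPM against 231 ± 1.75 CPM (SD, n = 2 clone labels; log2 change 0.34 ± 0.09, adjusted p = 0.0293 in edgeR). The gene lies on chromosome 11, whose genes as a whole were higher in MD, and with each chromosome scaled separately both changes turned negative, to -0.39 in ESC, which passed (adjusted p = 0.0125 in edgeR, and 0.0125 to 0.971 over the alternatives), and to -0.14 in neural cells, which did not. Without the label 09 or the label 30 the neural change was 0.32 and 0.37 and did not pass. The tag acts on the protein, so the RNA level does not check which libraries carry the active form.

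The first comparison asks which genes differ between MD and R42A in ESC. MD clones had less RNA of 15 of 26 naive pluripotency genes and more of 8 of 15 formative genes, 3 of which fell. No list call held with an estimated correlation. Klf4 and Tbx3, transcription factors of the naive network, fell by 1.07 ± 0.06 and 1.40 ± 0.10 on the log2 scale. They went from 152 ± 55.5 to 71.7 ± 24.5 CPM and from 79.3 ± 9.07 to 30.3 ± 6.46 CPM (SD, n = 4 clones). Dnmt3b, a de novo DNA methyltransferase that rises as ESC leave the naive state, rose from 169.6 ± 8.54 to 372 ± 41.3 CPM. Nes, the neural progenitor intermediate filament nestin, rose from 17.6 ± 2.87 to 57.9 ± 18.8 CPM, and H19, an imprinted non-coding RNA, from 5.93 ± 3.15 to 67.5 ± 36.4 CPM. In edgeR, 7862 of 21567 tested genes changed, 3680 higher and 4182 lower in MD. Of these, 1291 were higher and 917 lower by at least 2-fold.

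**Figure D1:**
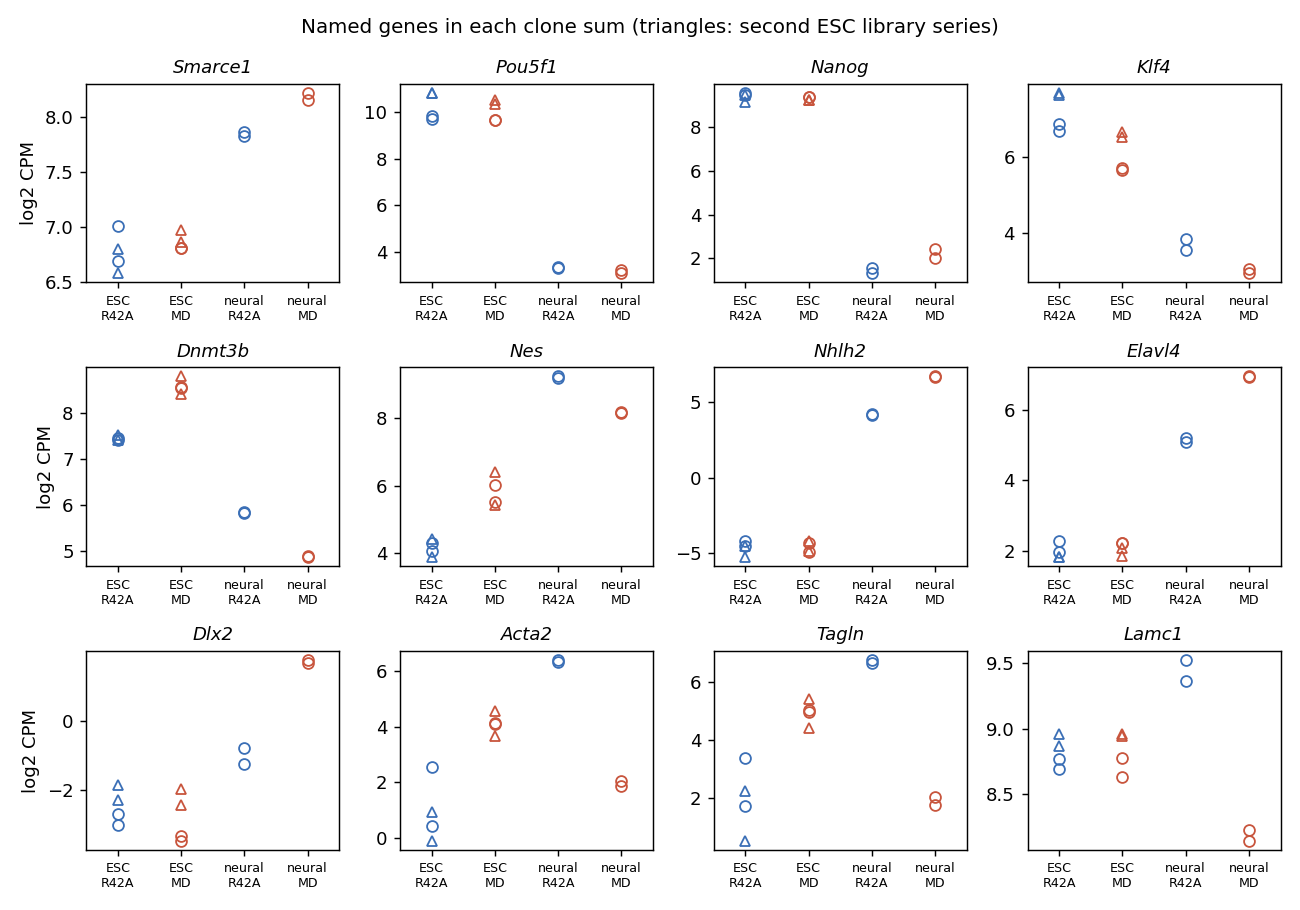
Log2 CPM of 12 genes in each clone sum, R42A in blue and MD in red, for ESC and neural cells; triangles are the second ESC library series and each panel has its own axis. Klf4 is lower and Dnmt3b, Nes, Acta2 and Tagln are higher in MD than in R42A ESC, while Nes, Acta2 and Tagln are lower in MD neural cells.

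Of 26 naive pluripotency genes, 2 rose and 15 fell (3 and 15 adjusted over the list alone), and camera placed the list lower (adjusted p = 0.00865, and 0.595 with an estimated correlation). Esrrb and Fgf4 fell by 0.72 ± 0.05 and 0.54 ± 0.05. Pou5f1, which encodes OCT4, fell by 0.24 ± 0.08 (adjusted p = 0.0346 in edgeR). That call was lost without any 1 of the clones A04, A01, A02, 09, 45 or 47, with log2 changes of -0.27 to -0.18 and adjusted p between 0.0560 and 0.0981, and in the first series alone, where the change was -0.058. Sox2 and Nanog had log2 changes of 0.11 ± 0.06 and -0.10 ± 0.07 that did not pass (adjusted p = 0.151 and 0.298 in edgeR), and the Nanog value turned to 0.067 with each chromosome scaled separately. Without clone 45, Sox2 passed at 0.16 (adjusted p = 0.0442 in edgeR, 0.00992 to 0.827 over the alternatives). It also passed at 0.14 with libraries as replicates, without and with the replicate block (adjusted p = 0.0135 and 0.0194 in edgeR). Of 15 formative and primed genes, 8 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0289, and 0.595 with an estimated correlation). Dnmt3b rose by 1.13 ± 0.08 and Pou3f1, an early neural POU factor, by 1.52 ± 0.17, while Etv4, an FGF-responsive ETS factor on chromosome 11, fell by 0.74 ± 0.08. The adjusted p of these 5 genes in edgeR was at most 0.000261.

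Neural progenitor genes rose more often than they fell, with 8 up and 1 down of 21 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00865, and 0.595 with an estimated correlation). Nes rose by 1.71 ± 0.22 (adjusted p = 0.000585 in edgeR), Cdh2, which encodes N-cadherin, by 1.65 ± 0.21, and the proneural factor Neurog1 by 1.92 ± 0.27, at a level of only 0.354 ± 0.0689 CPM in MD. Hox genes, which set position along the body axis, fell in 10 of 17 cases and rose in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 0.00865, and 0.595 with an estimated correlation). Hoxa4 fell by 2.61 ± 0.36, from 0.332 ± 0.0415 CPM, and so was at the low end of detection. Hoxb9 fell by 1.60 ± 0.20, from 1.56 ± 0.365 to 0.514 ± 0.125 CPM. Fibroblast and mesenchyme genes rose in 10 and fell in 3 of 15 cases (11 and 3 adjusted over the list alone; camera adjusted p = 0.0147, 0.0803 with single libraries, and 0.595 with an estimated correlation). Among them the smooth muscle genes Acta2 and Tagln rose by 2.95 ± 0.51 and 2.80 ± 0.49 (adjusted p = 0.00252 and 0.00268 in edgeR), to 17.3 ± 4.29 and 31.2 ± 8.47 CPM. In the first series alone neither passed, at log2 changes of 2.31 and 2.30, nor did Tagln in the second, at 3.41. Trophectoderm genes rose in 8 and fell in 3 of 16 cases (9 and 4 adjusted over the list alone; camera adjusted p = 0.0398, 0.218 with single libraries, 0.0622 with each chromosome scaled separately, and 0.595 with an estimated correlation). Endothelium and blood genes rose in 5 and fell in 0 of 10 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00865, and 0.595 with an estimated correlation), among them Kdr, a VEGF receptor, by 1.92 ± 0.20.

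Imprinted genes rose in 14 and fell in 1 of 29 cases (15 and 1 adjusted over the list alone), and camera gave an adjusted p of 0.000280, and 0.156 with an estimated correlation. H19 rose by 3.60 ± 0.46, and Peg3 and Usp29, neighbours on chromosome 7, by 1.07 ± 0.08 and 1.21 ± 0.12. Genes of hypoxia and glycolysis fell in 13 and rose in 0 of 19 cases (15 and 0 adjusted over the list alone; camera adjusted p = 1.4e-05, and 0.595 with an estimated correlation). Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, fell by 0.61 ± 0.04. The phosphofructokinase gene Pfkp fell by 0.79 ± 0.06, and Ankrd37, a HIF target on chromosome 8, by 1.27 ± 0.11. Over the alternatives the log2 change of Ankrd37 ran from -1.34 to -0.80. Interferon response genes rose in 8 and fell in 1 of 18 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0316, 0.0598 with each chromosome scaled separately, and 0.595 with an estimated correlation). Isg15 and Ifit1 rose by 3.71 ± 0.66 and 2.26 ± 0.38, to levels of only 0.655 ± 0.121 and 0.593 ± 0.143 CPM. Wnt response genes rose in 9 and fell in 1 of 16 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0158, 0.117 with each chromosome scaled separately, and 0.595 with an estimated correlation). Of these, the Wnt feedback gene Znrf3 on chromosome 11 rose by 0.73 ± 0.06, with log2 changes of 0.24 to 0.78 over the alternatives.

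2-cell-like genes fell in 10 and rose in 0 of 20 cases (12 and 0 adjusted over the list alone; camera adjusted p = 0.0119, and 0.660 with an estimated correlation). Zscan4a, a marker of the 2-cell-like state, fell by 1.78 ± 0.48 (adjusted p = 0.0183 in edgeR), but its clones overlapped, its reads can be shared with near-identical copies, and the call was lost without A04, A01, 09 or 45 (adjusted p between 0.0567 and 0.104; log2 change -1.14 without A04 and -1.69 to -1.65 without the others). Germline genes rose in 9 and fell in 2 of 23 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0398, 0.0803 with single libraries, 0.0648 with each chromosome scaled separately, and 0.659 with an estimated correlation). G2/M genes fell in 12 and rose in 4 of 24 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0265, 0.0803 with single libraries, and 0.595 with an estimated correlation). The spindle checkpoint kinase gene Bub1b fell by 0.44 ± 0.04, while Top2a, the DNA topoisomerase of dividing cells on chromosome 11, rose by 0.45 ± 0.05 and had a change of -0.026 with each chromosome scaled separately. Replication histones, whose reads can be shared among copies, rose in 7 and fell in 2 of 20 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0434, 0.191 with single libraries, 0.0598 with each chromosome scaled separately, and 0.660 with an estimated correlation). Y-linked genes rose in 2 and fell in 0 of 6 (2 and 0 adjusted over the list alone; camera adjusted p = 0.0252, and 0.595 with an estimated correlation).

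Of 27 SWI/SNF subunit genes, 5 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.877). Smarcd3, a subunit gene linked to neural and muscle development, fell by 1.34 ± 0.12, Brd9 of the non-canonical complex by 0.38 ± 0.06 and Brd7 of the PBAF complex by 0.58 ± 0.08, while the PBAF gene Phf10 rose by 0.38 ± 0.07. Brd7 lies on chromosome 8, and its change was -0.09 and did not pass with each chromosome scaled separately. The other lists did not pass in camera, with adjusted p between 0.0629 and 0.674. For neurons 5 genes rose and 2 fell of 21, for glia 2 and 0 of 10 (0 and 0 adjusted over the list alone), for forebrain 1 and 3 of 13, for midbrain and hindbrain 4 and 1 of 13, for mesoderm 6 and 3 of 21, for endoderm 4 and 4 of 23, for neural crest 4 and 1 of 13, and for surface ectoderm 4 and 2 of 14. For G1/S genes 3 rose and 8 fell of 23, for p53 targets 3 and 9 of 20, for immediate early and stress genes 4 and 4 of 19, for the Nodal/TGFb/BMP response 6 and 2 of 15 and for FGF/ERK 4 and 2 of 14. For Notch 7 rose and 2 fell of 14, for Hedgehog 2 and 1 of 11, for cholesterol synthesis 0 and 2 of 18 and for mitochondrially encoded genes 0 and 2 of 11. Egr1, an immediate early transcription factor, rose by 1.56 ± 0.17 (adjusted p = 0.000281 in edgeR).

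Among single genes outside these themes, Enpp2, which encodes the secreted enzyme autotaxin, rose by 4.32 ± 0.48, from 0.987 ± 0.734 to 19.2 ± 5.86 CPM (adjusted p = 0.000272 in edgeR). Gbp2, a guanylate binding protein gene with close copies that can share reads, rose by 4.27 ± 0.72. The actin-binding gene Coro2b fell by 2.76 ± 0.08, from 19.8 ± 3.82 to 2.93 ± 0.554 CPM (adjusted p = 3.3e-06 in edgeR), and the small GTPase gene Mras by 2.47 ± 0.14, from 79.7 ± 18.0 to 14.3 ± 0.923 CPM.

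The MD effect had the same sign for most genes in both ESC library series, which hold different clones. Each alone gave 1769 changed genes in the first and 4878 in the second (2 clones against 2). Across 20854 genes, which are not independent replicates, Pearson's r between the log2 changes was 0.814 and Spearman's rho 0.776. Of 1730 genes called in the first series, 1727 had the same sign in the second, and of 4859 called in the second, 4788 had the same sign in the first. A test of series by genotype called 0 genes in edgeR, with 644 at an unadjusted p under 0.05, and 7 genes in DESeq2. In both series the MD clones lay apart from the R42A clones on chromosomes 8 and 11. Agreement between the series therefore cannot tell an effect of MD from a history shared by the lines of a genotype. Klf4, Phf10, Pou5f1, Top2a and Zscan4a did not pass without the series term, where 3084 genes were called.

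Genes of chromosome 11 were higher and genes of chromosome 8 lower in MD, in ESC along the whole chromosome. In neural cells the first 10 Mb of chromosome 8 had a median of only -0.12 (23 genes). On chromosome 11 the median log2 difference was 0.46 in the first ESC series, 0.51 in the second and 0.49 in neural cells, and at least 93.7% of its genes were higher in MD. On chromosome 8 it was -0.43, -0.53 and -0.37, and at most 12.5% of genes were higher in MD. The largest shift among the 18 other chromosomes was 0.18 in size. The chromosome 11 deviation of the ESC clones was 0.24 ± 0.01 in MD and -0.24 ± 0.04 in R42A (SD, n = 4 clones), and that of chromosome 8 was -0.24 ± 0.03 and 0.24 ± 0.15. For both, a two-sided exact permutation test over the 36 assignments of clones within the library series gave p = 0.0556, the smallest it can give, and 0.111 adjusted over 20 chromosomes, so it cannot pass. The planned test over all 70 assignments, which ignores the series, gave 0.0286, and 0.0571 adjusted. The same p values were reached by 8 other chromosomes (6, 7, 9, 10, 14, 15, 17 and X) with MD less R42A differences of only -0.16 to -0.04, so size and not p sets chromosomes 8 and 11 apart. The R42A clones were not alike. On chromosomes 6, 14, 15 and X their excess lay mainly in A10 and A02, on chromosome 6 at 0.11 and 0.17 against 0.04 in A04 and 0.01 in A01. On chromosome 8 the deviation was 0.05 in A10 and 0.39 in A04. Chromosomes 8 and 11 hold 21.2% of the genes called in ESC and 12.5% of those tested, and 17.4% and 12.2% in neural cells.

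**Figure D2:**
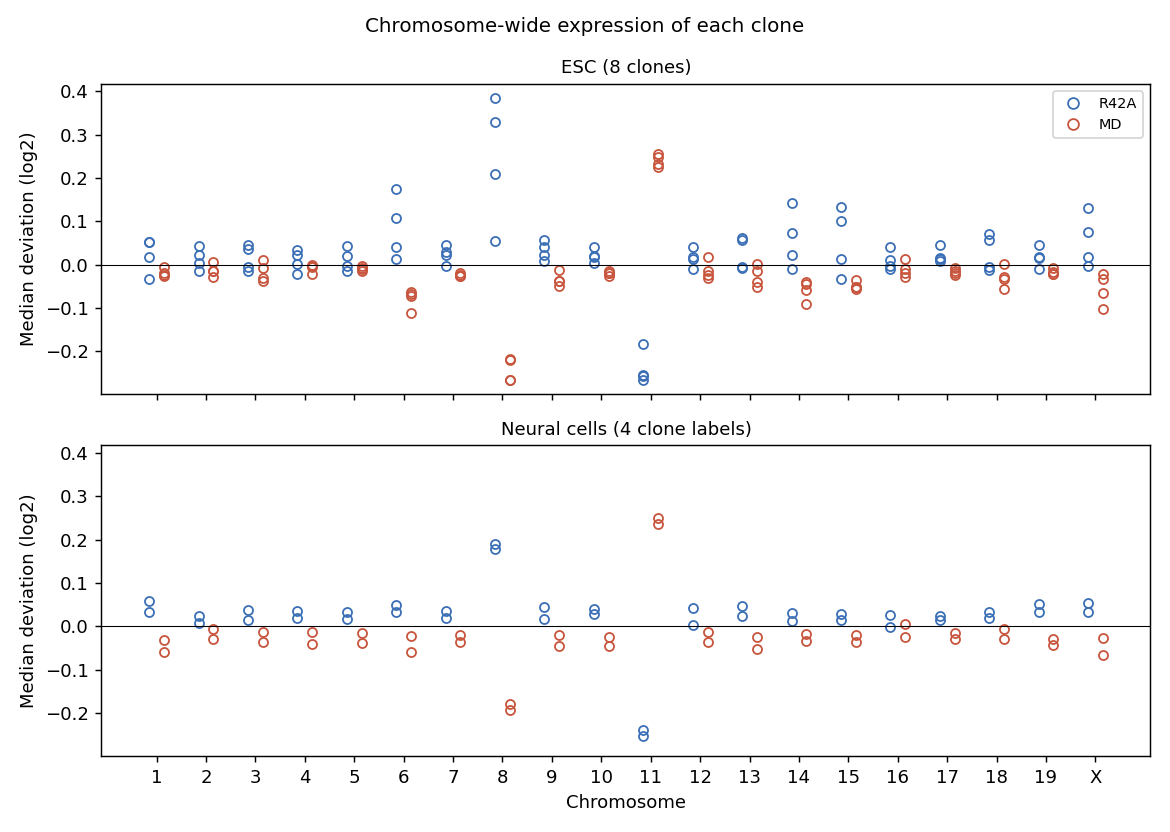
Median log2 deviation of the genes of each chromosome from the mean of the clones of the same library series, one circle per clone, R42A in blue and MD in red, for ESC above and neural cells below. Chromosome 11 is higher and chromosome 8 lower in MD clones at both stages, with ESC means of 0.24 against -0.24 on chromosome 11.

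The next comparison asks how MD and R42A differ after 6 days in neural medium. MD cultures had more RNA of nearly every neuronal gene tested and less of Nes, Tagln and Acta2, of 13 of 26 endoderm genes and of 8 of 14 surface ectoderm genes. No list call held with an estimated correlation. Tubb3, the neuronal tubulin, was at 601 ± 0.258 CPM in MD and 277 ± 6.18 CPM in R42A (SD, n = 2 clone labels), and Nhlh2, a transcription factor of newborn neurons, at 100.2 ± 2.42 and 17.9 ± 0.133 CPM. Nes was lower, at 286 ± 5.30 against 593 ± 9.57 CPM, and the smooth muscle genes Tagln and Acta2 fell to 3.71 ± 0.493 and 3.90 ± 0.364 CPM from 105 ± 4.31 and 82.5 ± 1.22 CPM. In edgeR, 8030 of 23844 tested genes changed, 4152 higher and 3878 lower in MD, with 1539 and 1010 of them by at least 2-fold.

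Of 25 neuron genes, 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 change of 1.49 and a camera adjusted p of 9.04e-13, and 0.260 with an estimated correlation. Nhlh2 rose by 2.49 ± 0.08, the RNA-binding protein gene Elavl4 by 1.77 ± 0.10, the neurofilament gene Nefl by 1.65 ± 0.09 and the homeobox gene Onecut1 by 1.64 ± 0.09, all with adjusted p of at most 9.83e-05 in edgeR. Tubb3 rose by 1.12 ± 0.29 (adjusted p = 0.0234 in edgeR). Among 25 neural progenitor genes, 8 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.237). The proneural factor Neurog2 rose by 2.40 ± 0.17, while Nes fell by 1.05 ± 0.15 (adjusted p = 0.00241 in edgeR) and the Notch-pathway gene Hes3 by 1.46 ± 0.13. Sox1 and Pax6, markers of neuroectoderm, had log2 changes of -0.47 ± 0.31 and 0.43 ± 0.35 that did not pass (adjusted p = 0.283 and 0.399 in edgeR). Pax6 passed without A04 and without A10, at 0.44 and 0.43, and with the neural clone sums alone, at 0.44. Sox1 passed in limma voom, at -0.47 (adjusted p = 0.0121, and 7.73e-14 to 0.775 over the alternatives), and with the neural clone sums alone, also at -0.47. Sox2 rose by 0.44 ± 0.05 and Nanog, at only 4.71 ± 0.960 CPM, by 0.80 ± 0.14, while Pou5f1 changed by -0.17 ± 0.07 and did not pass (adjusted p = 0.100 in edgeR, 0.0499 without A04 and 0.0273 to 0.658 over the alternatives). Of 17 forebrain genes 8 rose and 0 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0634). Lhx2, a forebrain homeobox gene, rose by 1.86 ± 0.10, and Dlx1 and Dlx2, homeobox genes of inhibitory neuron precursors, by 2.95 ± 0.21 and 2.71 ± 0.22.

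Endoderm genes fell in 13 and rose in 1 of 26 cases (17 and 1 adjusted over the list alone; camera adjusted p = 7.35e-06, and 0.591 with an estimated correlation). The laminin gene Lamc1 fell by 1.27 ± 0.08, the transthyretin gene Ttr by 1.72 ± 0.13 and the apolipoprotein gene Apoe by 1.45 ± 0.14. Apob, an apolipoprotein gene of liver, gut and yolk sac, fell by 4.60 ± 0.32, from 18.6 ± 0.700 to 0.767 ± 0.00412 CPM. Surface ectoderm genes fell in 8 and rose in 1 of 14 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00159, and 0.591 with an estimated correlation). E-cadherin, encoded by Cdh1 on chromosome 8, fell by 1.12 ± 0.11 and the desmosomal gene Perp fell by 1.80 ± 0.10. Over the alternatives the log2 change of Cdh1 ran from -1.19 to -0.74. Of 17 fibroblast and mesenchyme genes 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.669), and Tagln and Acta2 fell by 4.82 ± 0.51 and 4.40 ± 0.60 (adjusted p = 0.000681 and 0.00179 in edgeR).

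G1/S genes fell in 15 and rose in 2 of 23 (17 and 2 adjusted over the list alone; camera adjusted p = 9.57e-05, and 0.260 with an estimated correlation). G2/M genes fell in 14 and rose in 3 of 24 (16 and 3 adjusted over the list alone; camera adjusted p = 0.000111, and 0.538 with an estimated correlation). Cyclin E1, encoded by Ccne1, fell by 0.67 ± 0.04 and the mitotic kinase gene Plk1 by 0.67 ± 0.05. Of 20 p53 targets 14 fell and 1 rose (15 and 1 adjusted over the list alone; camera adjusted p = 4.32e-05, and 0.260 with an estimated correlation), among them Perp and Gtse1. Gtse1, a G2 and S phase gene, fell by 0.71 ± 0.06. Genes of cholesterol synthesis fell in 9 and rose in 0 of 18 (11 and 0 adjusted over the list alone; camera adjusted p = 4.38e-05, and 0.714 with an estimated correlation), with Idi1 down by 1.18 ± 0.15. FGF/ERK response genes fell in 7 and rose in 2 of 14 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00831, and 0.657 with an estimated correlation), among them Etv5 by 0.98 ± 0.06 and Dusp6, a phosphatase that limits ERK signalling, by 1.08 ± 0.14. Mitochondrially encoded genes fell in 6 and rose in 0 of 11 (7 and 0 adjusted over the list alone; camera adjusted p = 0.00498, and 0.538 with an estimated correlation), with mt-Nd5 down by 0.63 ± 0.04. The 2-cell-like list had a median of -3.59, or -3.15 with genes of 0 counts at their floor (camera adjusted p = 0.000482, and 0.718 with an estimated correlation), although 0 of 20 members passed in edgeR, 2 had an unadjusted p under 0.05, and 12 passed in DESeq2.

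Pfkp and Pdk1, lower in MD ESC, rose by 1.94 ± 0.10 and 0.96 ± 0.08 in neural MD cells, where 9 of 19 hypoxia and glycolysis genes rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.121). Of 28 SWI/SNF subunit genes 9 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.406). Actl6b, which encodes the neuronal subunit BAF53B, rose by 2.50 ± 0.22, and Actl6a, which encodes its progenitor counterpart BAF53A, fell by 0.38 ± 0.05. The membrane peptidase gene Mme fell by 3.48 ± 0.14, from 66.3 ± 0.579 to 5.94 ± 0.185 CPM.

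**Figure D3:**
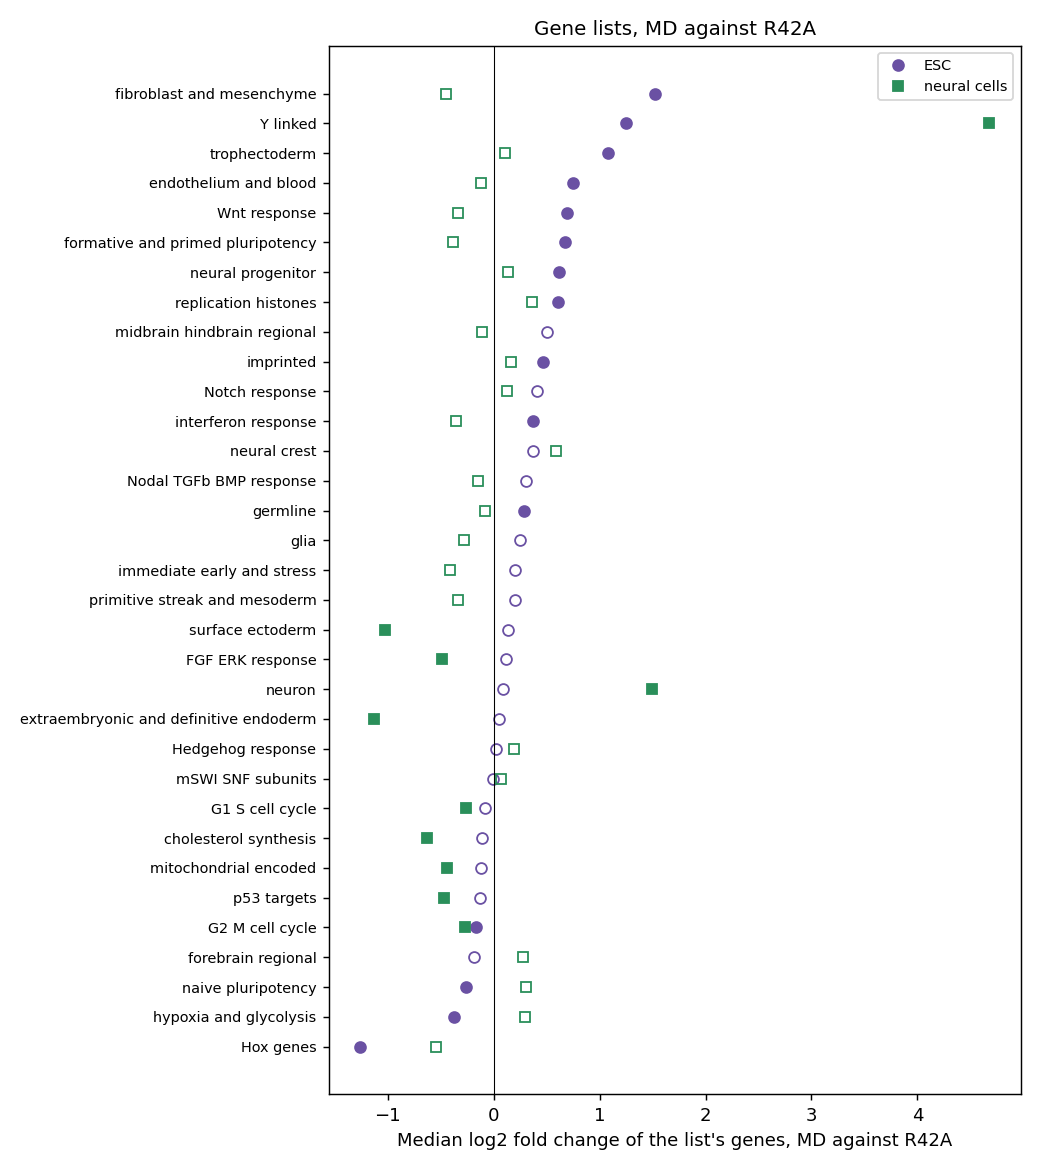
Median log2 change, MD against R42A, of the genes of each list in ESC (circles) and neural cells (squares), for the lists other than the 2-cell-like list; filled symbols have a camera adjusted p under 0.05 with the preset correlation. The neuron list lies at 1.49 in neural cells and at 0.09 in ESC.

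All 6 Y-linked genes rose in neural MD cells (6 and 0 adjusted over the list alone; camera adjusted p = 0.000150, and 0.400 with an estimated correlation), with Kdm5d up by 4.43 ± 0.21 and Ddx3y by 4.46 ± 0.81. The summed level of these genes was 6.30 and 7.02 CPM in the neural libraries labelled A04 and A10, and 171 and 163 CPM in those labelled 09 and 30. In ESC it was 162 ± 29.3 CPM (SD, n = 3 libraries) in A04, 29.3 ± 1.31 in A10, 109 in A01 and 6.28 in A02, and 216, 212, 165 and 163 CPM in 09, 30, 45 and 47. Reads of these genes can be shared with their X-linked copies. The neural libraries labelled A04 and A10 were as close to each other (median absolute log2 ratios of 0.0450 to 0.0790, over genes with at least 500 counts) as libraries of the same label (0.0674 to 0.0849).

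**Figure D4:**
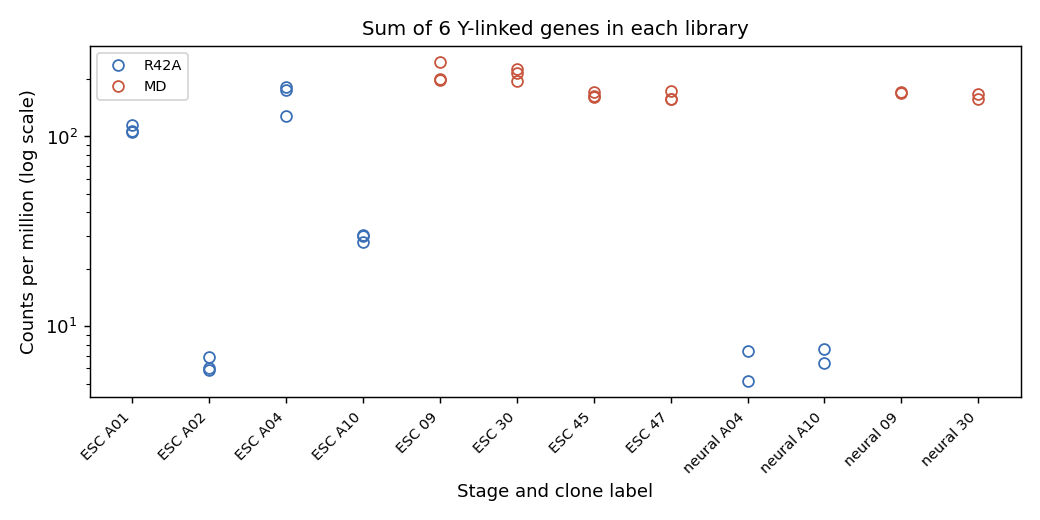
Summed CPM, on a log scale, of 6 Y-linked genes in each library, R42A in blue and MD in red, by stage and clone label. The libraries labelled A04 lie near 162 CPM in ESC and near 6.30 CPM in neural cells.

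The neural p-values rest on 2 clone labels per genotype, with the spread shared with ESC of the same labels, and libraries of the 2 labels of a genotype were as close as libraries of 1 label (0.0579 to 0.0707 against 0.0392 to 0.0871 in MD). Without the label 09 the count was 1600 and without 30 it was 1538, a lone sample then being assumed to vary like the others, and with the 4 neural clone sums alone, whose spread is that between labels that lie close, it was 13643. Tubb3, Tagln, Acta2, Idi1, Ddx3y and Dusp6 did not pass without 09 or without 30 (adjusted p between 0.0501 and 0.185), although their log2 changes hardly moved: 1.12 and 1.12, -4.97 and -4.69, -4.50 and -4.31, -1.23 and -1.14, 4.43 and 4.48, and -1.09 and -1.07. Nor did Actl6a pass without 30 (-0.36), Nanog without 09 or A10 (0.57 and 0.70), or Nes without A04 or A10 (-1.06 and -1.03), with adjusted p between 0.0511 and 0.106.

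The comparison of neural cells with ESC describes the course of differentiation in each genotype. Both genotypes lost pluripotency RNA and gained neural progenitor and neuronal RNA. In R42A, Pou5f1 fell by 6.49 ± 0.08 on the log2 scale, from 895 ± 58.1 to 9.95 ± 0.127 CPM, and in MD it fell by 6.58 ± 0.08 (SD, n = 2 clone labels). Zic1, a neural zinc finger gene, was at most at 0.0489 ± 0.0188 CPM in ESC and at 268 ± 13.5 and 240.1 ± 3.36 CPM in neural R42A and MD cells. In edgeR, 18671 of 23844 genes changed in R42A (9031 higher and 9640 lower) and 19392 in MD (9611 higher and 9781 lower). Stage and library series cannot be told apart in these counts.

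All 25 neural progenitor genes rose in both genotypes (camera adjusted p = 1.89e-10 in R42A and 9.96e-10 in MD, and 0.208 and 0.241 with an estimated correlation). Sox1 rose by 4.26 ± 0.35 in R42A and 5.29 ± 0.37 in MD, Pax6 by 3.36 ± 0.39 and 2.81 ± 0.38, Nes by 4.98 ± 0.18 and 2.30 ± 0.16, Pou3f2 by 11.11 ± 0.16 and 10.28 ± 0.15, and the Notch target Hes5 by 8.50 ± 0.13 and 7.98 ± 0.13. Neuron genes rose in 21 and fell in 2 of 25 in R42A, and rose in 22 and fell in 1 in MD (camera adjusted p = 4.91e-06 and 1.23e-07, and 0.204 and 0.241 with an estimated correlation). Tubb3 rose by 2.29 ± 0.30 in R42A and 3.63 ± 0.32 in MD, and Nhlh2 by 11.61 ± 0.15 in MD. Forebrain genes rose in 15 and fell in 1 of 17 in both genotypes, and midbrain and hindbrain genes rose in 14 and fell in 2 of 17. The adjusted p was at most 0.000609 in camera for both lists and both genotypes, and at least 0.185 with an estimated correlation. The forebrain and midbrain gene Otx1 rose by 8.94 ± 0.21 and 8.78 ± 0.21 and the dorsal gene Pax7 by 7.81 ± 0.12 and 8.33 ± 0.12. Wnt1 and Tfap2b had 0 counts in R42A ESC and were at least 2762-fold and 5043-fold higher in R42A neural cells, against 3 counts over the group.

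Of 26 naive pluripotency genes, 25 fell and 0 rose in R42A, and 25 fell and 1 rose in MD (camera adjusted p = 5.94e-11 and 9.49e-10, and 0.204 and 0.241 with an estimated correlation). Esrrb fell by 6.81 ± 0.09 in R42A and 5.55 ± 0.08 in MD. Germline genes fell in 22 and rose in 0 of 23 in both (camera adjusted p = 2.02e-07 and 1.23e-07, and 0.189 and 0.185 with an estimated correlation), where Tex14 fell by 8.28 ± 0.10 in R42A and fell by 6.14 ± 0.09 in MD, and Dazl fell by 6.84 ± 0.19 and fell by 7.82 ± 0.20. Stra8, a gene of meiotic entry, had 0 counts in R42A neural cells and was at least 2025-fold lower than in R42A ESC. Dnmt3b fell by 3.74 ± 0.05 in MD. SWI/SNF subunit genes rose in 20 and fell in 4 of 28 in R42A and rose in 20 and fell in 5 in MD (camera adjusted p = 0.00144 and 0.00364, and 0.358 and 0.344 with an estimated correlation). Smarca2, one of the ATPase genes of the complex, rose by 5.29 ± 0.16 and 4.54 ± 0.16, Smarcc2 by 2.07 ± 0.04 and 2.64 ± 0.05, and Smarce1 by 0.95 ± 0.10 and 1.31 ± 0.10. Cxcr4, a chemokine receptor gene, rose by 6.35 ± 0.09 and 7.66 ± 0.10. Across 23844 genes, which are not independent replicates, the 2 log2 changes had r = 0.911, 88.7% had the same sign, and 435 genes were called in opposite directions.

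The last comparison asks for which genes the MD effect differed between neural cells and ESC of the same clone labels. The effect on Tagln reversed: it was higher in MD ESC (34.0 against 7.01 CPM) and lower in MD neural cells (3.71 against 105 CPM), a difference of -7.09 ± 0.68 on the log2 scale between the effects. Acta2 differed by -6.69 ± 0.81, the myosin light chain gene Myl9 by -5.34 ± 0.22 and the matrix gene Thbs1 by -4.28 ± 0.70. In the other direction, the sodium channel gene Scn3a was lower in MD ESC (3.68 against 13.6 CPM) and higher in MD neural cells (71.7 against 11.7 CPM), a difference of 4.51 ± 0.30. The neurexophilin gene Nxph4 differed by 3.92 ± 0.19. In edgeR the effect differed for 5472 of 23844 genes, 2830 with a higher and 2642 with a lower effect in neural cells. Of 34 lists, 20 passed in camera with the preset correlation, 4 with a higher and 16 with a lower effect in neural cells. Only a part of these lists is given below.

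Neuron genes had a higher effect in neural cells in 15 and a lower effect in 0 of 25 cases (16 and 0 adjusted over the list alone; camera adjusted p = 1.36e-06, and 0.329 with an estimated correlation), among them Elavl3 by 1.70 ± 0.12 and Stmn2 by 1.90 ± 0.17. Among 25 neural progenitor genes 6 had a higher and 5 a lower effect (7 and 6 adjusted over the list alone; camera adjusted p = 0.644), with Nes at -2.68 ± 0.22 and Cdh2 at -1.48 ± 0.11. Of the formative genes 1 had a higher and 9 a lower effect of 15 (1 and 9 adjusted over the list alone; camera adjusted p = 0.00290, and 0.329 with an estimated correlation), with Dnmt3b at -2.12 ± 0.06 and Fgf5 at -5.40 ± 0.69. Of the naive genes 11 had a higher and 3 a lower effect of 26 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00887, and 0.468 with an estimated correlation), with Esrrb at 1.26 ± 0.10 and Tet2 at 1.34 ± 0.15. Hypoxia and glycolysis genes had a higher effect in 10 and a lower effect in 0 of 19 (11 and 0 adjusted over the list alone; camera adjusted p = 5.05e-05, and 0.434 with an estimated correlation), with Pfkp at 2.80 ± 0.15, Vegfa at 1.71 ± 0.17 and Pdk1 at 1.57 ± 0.11. Surface ectoderm genes had a lower effect in 9 and a higher effect in 0 of 14 (9 and 0 adjusted over the list alone; camera adjusted p = 5.05e-05, and 0.329 with an estimated correlation), with Perp at -1.80 ± 0.14. Endoderm genes had a lower effect in 9 and a higher effect in 1 of 26 (12 and 1 adjusted over the list alone; camera adjusted p = 5.22e-05, and 0.434 with an estimated correlation), with Lamb1 at -1.81 ± 0.21. Apob was at -5.00 ± 0.42, Kdr at -3.61 ± 0.33, Lhx2 at 2.25 ± 0.17, Ccne1 at -0.84 ± 0.06 and Peg3 at -0.97 ± 0.08. Of the SWI/SNF genes, Actl6b was at 3.66 ± 0.49, Actl6a at -0.64 ± 0.07 and Smarcc2 at 0.57 ± 0.06. Actl6b was near the floor in ESC, at 0.0537 CPM in R42A and 0.0230 CPM in MD, and Nxph4, Fgf5 and Lhx2 were also under 1 CPM in some groups. Smarce1 at 0.36 ± 0.13 did not pass (adjusted p = 0.0995 in edgeR, 0.000134 without A10 and 0.000134 to 0.445 over the alternatives).

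The called genes named in this comparison had adjusted p of at most 0.00645 in edgeR. Without the label 09 the count was 77 and without 30 it was 114, while without A04 it was 8759. Myl9, Nxph4, Nes, Dnmt3b, Pfkp and Pdk1 passed in each of these fits. The other called genes did not pass without 09 or without 30 or both (adjusted p between 0.0516 and 0.148), although values such as those of Tagln (-7.22 and -6.99), Scn3a (4.43 and 4.59) and Stmn2 (1.95 and 1.85) hardly moved, and Fgf5 did not pass without A04 or A10 either. Across 21470 genes, which are not independent replicates, the MD effects in ESC and in neural cells had r = 0.153 and rho = 0.187. Of the genes called at both stages, 1279 were higher and 1277 lower in MD at both, against 639.8 and 725.3 expected for independent calls, and 989 went in opposite directions. Much of this excess came from chromosomes 8, 11 and Y. Without them r was 0.120 and rho 0.123, and 614 genes were higher and 980 lower at both stages, against 401.4 and 613.4 expected, with 910 in opposite directions.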

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

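The tests of explanations in this part, and the counts over other splits of the clones, were chosen only after the results were seen, while the test of the difference between stages was planned.

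Genes of chromosomes 11 and 8 differed between MD and R42A clones at both stages. A change at a few loci is argued against by the windows of 10 Mb along both chromosomes, whose median differences in ESC were at least 0.348 in size, while in neural cells those of chromosome 8 ran from -0.50 to -0.12 and leave its first 10 Mb open. A single scaling factor per library is argued against by the other chromosomes, whose medians were at most 0.181 in size. Dosage of 3 copies against 2 may explain the chromosome 11 shift, since the log2 of that ratio, 0.585, lies between the quartiles of its gene differences in the second ESC series (0.36 to 0.64) and in neural cells (0.29 to 0.70) and just above them in the first (0.30 to 0.58), but copy number was not measured. An effect of MD and the history of the lines cannot be told apart, because 4 of 4 MD ESC clones had chromosome 11 higher than the R42A clones. The deviations are taken from the mean of both genotypes in a series. Whether MD clones were raised or R42A clones lowered therefore cannot be told either.

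The number of genes that differ between MD and R42A in ESC was 7862. The calls were not confined to genes of chromosomes 8, 11 and Y, since 5948 genes were called without them, but whether the dosage of those chromosomes drives changes elsewhere was not tested. Of the splits of the 8 ESC clones, 18 keep 2 clones of each series in either group as the real one does, too few for a share under 0.05. Of these 1, the real one, gave as many genes, and every other gave 0 in edgeR, the one with the most at an unadjusted p under 0.05 having 2826 of these and 507 genes in DESeq2. Each other split mixes MD and R42A clones within a group, so their difference adds to the spread and lowers the calls. The counts of the other splits therefore do not show what a grouping of like clones would give. For the 16 lists that passed in camera, 2 of the 18 splits gave at least as many and the highest other gave 17, and over all 34 splits that could be fitted 1 gave as many genes and 4 as many lists. Splits with 2 MD and 2 R42A clones in either group, in which genotype cancels, still gave 3 to 14 lists. The number of lists that passed with the preset correlation therefore does not set the real split apart, and the list calls in ESC carry that limit.

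The neural libraries labelled A04 and A10 did not separate, nor did those labelled 09 and 30 (0.0579 to 0.0707 between labels, 0.0392 to 0.0871 within). One line under both R42A labels may explain this: the chromosome 8 median of A04 less A10 was -0.00660 in neural cells and 0.32 in ESC, while that of 09 less 30 was 0.0127 and 0.00131. A loss of chromosome 8 and Y-linked signal during culture of A04 cannot be told apart from it, since neural A04 had 6.30 CPM of Y-linked genes against 162 in ESC A04 and no library was taken on an intermediate day. An exchange of libraries between the genotypes is argued against by the smallest distance between genotypes among neural libraries, 0.219 as a median absolute log2 ratio, against at most 0.0871 within a genotype. If both neural labels hold 1 line, the neural R42A group has 1 replicate. The sums of both labels were nevertheless fitted as separate samples, so their small difference enters the spread shared by the 4 groups. The p-values of that fit may then be too small, and no fit with the labels merged was run. The Y-linked level of A10 also differed, at 29.3 CPM in ESC and 7.02 in neural cells, against 216 and 171 in 09 and 212 and 163 in 30. If the neural libraries labelled A04 or A10 are not of the ESC line of that label, the R42A comparison over time sets unlike lines against each other. The difference of the MD effect between stages then does so too.

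In 7 of 166 groups of 4 samples, 1 sample lay far from the other 3, where chance gives about 1 in 20. The values are the gap to the nearest sample divided by the range of the group. For Brd9 in ESC of MD clone 47 the value was 0.838 (log2 CPM 4.69 against 4.80 to 4.82). In library 1 of neural A10 it was 0.860 for Sox2 (7.76 against 7.80 to 7.81) and 0.866 for Sox1 (7.43 against 7.53 to 7.55). For Tagln in library 1 of neural A04 it was 0.906 (6.64 against 6.82 to 6.84). In neural 09 it was 0.944 for Ttr in library 2 (1.61 against 1.34 to 1.36) and 0.83 for Acta2 in library 1 (2.26 against 1.96 to 2.01). For the chromosome 11 deviation it was 0.858 in ESC clone A10 (-0.18 against -0.27 to -0.25).

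For 62 of 82 genes named in the text the MD effect differed between neural cells and ESC of the same labels (adjusted p under 0.05 for the difference itself in edgeR). Many of these genes were named because they had been called, some in this same test, so this share follows from the choice. Over all tested genes the share was 22.9% (5472 of 23844). Values below are the effect in neural cells less that in ESC, on the log2 scale. Without 09 and without 30, effects such as those on Tagln (-7.22 and -6.99), Scn3a (4.43 and 4.59) and Stmn2 (1.95 and 1.85) stayed about as large. The count of calls over all genes fell without 09 or 30 and rose without A04 or A10. Loss of a replicate alone therefore does not explain the lost calls. Without 09 or 30 the fitted spread comes only from A04 and A10, and without A04 or A10 only from 09 and 30. In ESC the median absolute log2 ratio between libraries of A04 and A10 had a median of 0.217. Between 09 and 30 it was 0.137. How far this unequal spread accounts for the lost calls was not tested. Neuronal and patterning genes were at Actl6b 3.66, Dlx1 3.35, Dlx2 3.28, Elavl3 1.70, Elavl4 1.64, Hoxa4 2.54, Hoxb9 1.13, Lhx2 2.25, Nefl 0.96, Nhlh2 2.72, Nxph4 3.92, Onecut1 1.16, Scn3a 4.51 and Stmn2 1.90. Progenitor genes were at Cdh2 -1.48, Hes3 -1.82, Nes -2.68 and Sox2 0.34. Pluripotency genes were at Dnmt3b -2.12, Esrrb 1.26, Fgf4 0.80, Fgf5 -5.40, Nanog 0.92, Pou3f1 -1.40 and Tet2 1.34. Smooth muscle, matrix, vessel and epithelial genes were at Acta2 -6.69, Tagln -7.09, Myl9 -5.34, Thbs1 -4.28, Kdr -3.61, Cdh1 -0.67 and Perp -1.80. Endoderm genes were at Apob -5.00, Apoe -1.12, Lamb1 -1.81, Lamc1 -1.27 and Ttr -2.10. Hypoxia and glycolysis genes were at Ankrd37 2.06, Pdk1 1.57, Pfkp 2.80 and Vegfa 1.71, and the cholesterol gene Idi1 at -0.90. Cell cycle and signalling genes were at Ccne1 -0.84, Gtse1 -0.42, Plk1 -0.55, Dusp6 -1.25, Egr1 -1.07, Etv5 -1.30 and Znrf3 -0.45. SWI/SNF genes were at Actl6a -0.64, Brd9 0.44, Smarcc2 0.57 and Smarcd3 1.27. Imprinted genes were at H19 -1.63, Peg3 -0.97 and Usp29 -0.33, and Y-linked genes at Kdm5d 1.97 and Zfy1 3.78. The others were Coro2b 2.98, Enpp2 -3.36, Mme -3.45 and Mras 2.52. The summed level of the Y-linked genes moved mainly in the R42A labels. From ESC to neural cells it went from 162 to 6.30 CPM in A04 and from 29.3 to 7.02 in A10. In 09 and 30 it went from 216 and 212 to 171 and 163 CPM. Kdm5d also rose in 09 and 30, from at most 4.76 CPM in an ESC library to at least 8.71 in a neural one.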

How the results depend on the processing

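Scaling each chromosome separately, leaving out chromosomes 8, 11 and Y, and exchanging 2 replicate numbers of the ESC clone A04 were chosen only after the results were seen, and the other alternatives were planned. In ESC, 7862 genes became 1463 in a test against a fold of 1.5, which asks for more, 3084 without the series term, 1769 in the first series alone and 4878 in the second (fewer clones each), and 5745 to 9329 with 1 clone left out. In neural cells, 8030 became 1715 against a fold of 1.5, 13643 with the 4 neural clone sums alone, and 1538 to 9967 with 1 label left out (1600 without 09 and 1538 without 30). The difference between stages went from 5472 to 1434 against a fold of 1.5 and to 77 to 8759 with 1 label left out (77 without 09, 114 without 30, 8759 without A04). A lone sample was then assumed to vary like the others. The stage comparisons gave 17072 to 18652 genes in R42A and 14428 to 20978 in MD with 1 label left out. The other alternatives stayed within 1.5 times each count, in ESC from 5948 without the 3 chromosomes to 10689 with the replicate block after the exchange of numbers. The lists depended on the correlation and, in ESC, on the libraries and the scaling. With an estimated correlation 0 lists passed in camera in ESC, against 16 with the preset one, 1 at an unadjusted p under 0.05 and 15 in fry. In neural cells this was 0 against 11, with 4 unadjusted and 17 in fry, in R42A over time 0 against 23, with 7 and 31, in MD over time 0 against 19, with 7 and 31, and for the difference between stages 0 against 20, with 3 and 19. Even the naive pluripotency list over time in R42A, with a median log2 change of -6.35, did not pass with the estimated correlation. That setting therefore cannot tell a real shift of a list from a false one here. With single libraries 11 of the 16 ESC lists passed, where trophectoderm (adjusted p = 0.218 in camera), replication histones (0.191) and the fibroblast, germline and G2/M lists (0.0803 each) did not. With each chromosome scaled separately 11 passed, where Wnt (0.117), germline (0.0648), trophectoderm (0.0622), and interferon and replication histones (0.0598 each) did not. In the other comparisons these 2 settings gave 12 and 15 lists in neural cells, 22 and 23 in R42A over time, 19 and 19 in MD over time, and 18 and 19 for the difference. Pearson's r between the ESC series was 0.814, and 0.888 at a mean log2 CPM of at least 3, 0.856 with libraries as replicates and 0.805 without the 3 chromosomes. Between ESC and neural cells it was 0.153, and 0.120 without the 3 chromosomes. The labels do not say whether libraries that share a number share a day or batch. After centring within each clone, libraries with the same number had median correlations of 0.295, 0.347 and 0.299 in the first series, the second and neural cells, and 10 of 12 libraries of each ESC series were best matched by their own number, so a batch per number is possible. The same-number values ran from -0.773 to 0.879 in the first series, -0.151 to 0.872 in the second and -0.0307 to 0.541 in neural cells. In the first series library 1 of A04 went with number 2 of A10, 09 and 30 (0.642, 0.861 and 0.774) and library 2 of A04 with number 1 of 09 and 30 (0.771 and 0.761), as if these numbers were exchanged, but only weakly with number 1 of A10 (0.282, against 0.777 with its number 3). The replicate block gave 10111 genes in ESC against 10110 without it, 8467 against 8538 in neural cells and 7179 against 7188 for the difference, and 10689, 9402 and 8182 with the 2 numbers exchanged. Of 147 results of named genes, 83 kept their direction and side of the threshold in every alternative and 4 changed direction, all with each chromosome scaled separately, a setting that removes whole-chromosome shifts: in ESC Smarce1 to -0.39 (adjusted p = 0.0125 in edgeR, 0.0125 to 0.971 over the alternatives), Nanog to 0.067 (0.325, and 0.0546 to 0.827) and Top2a to -0.026, and in neural cells Smarce1 to -0.14. The first series alone lost 12 named ESC calls and the second 4. Other than where stated, the cause of a change was not tested. Depth limits which genes can be tested: those under the count minimum of 10 were left out, and without this filter 7564 genes were called in ESC.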

Other observations

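The 6 further gene lists of this part, and the test of the explanation, were chosen only after the results were seen, and none was planned.

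Genes of the actin cytoskeleton and of SRF, the transcription factor that controls many of them, were higher in MD ESC and lower in MD neural cells. Of 13 genes, 8 rose and 0 fell in ESC, with a median log2 change of 1.10 (camera adjusted p = 2.87e-06, and 0.288 with an estimated correlation). In neural cells 12 fell and 0 rose, with a median of -2.60 (camera adjusted p = 1.64e-08, and 0.216 with an estimated correlation). For the difference between stages 13 of 13 had a lower effect in neural cells, with a median of -3.25 (camera adjusted p = 8.33e-12, and 0.164 with an estimated correlation). Srf itself rose by 0.54 ± 0.07 in ESC and fell by 0.71 ± 0.08 in neural cells. This list holds Acta2, Tagln and Myl9, whose values had been seen. Over time the list rose in R42A (9 up and 0 down, median 1.08, camera adjusted p = 0.0190, and 0.488 with an estimated correlation) and fell in MD (0 up and 11 down, median -1.73, camera adjusted p = 0.0124, and 0.421 with an estimated correlation).

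In neural cells, genes of GABAergic neurons were higher in MD, with 9 up and 0 down of 10 and a median of 2.83 (camera adjusted p = 3.56e-06, and 0.0557 with an estimated correlation). Gad2, which makes GABA, rose by 3.76 ± 0.23 and Slc32a1, its vesicle transporter, by 3.56 ± 0.28. Their effect differed from that in ESC in 7 of 10 cases, all higher in neural cells, with a median of 2.81 (camera adjusted p = 4.43e-06, and 0.0574 with an estimated correlation). Genes of glutamatergic neurons rose in 5 and fell in 0 of 7, with a median of 1.69 (camera adjusted p = 0.00556, and 0.216 with an estimated correlation), and the motor neuron list did not pass, with a median of 0.49 (camera adjusted p = 0.148). In ESC the medians of these 3 lists were -0.28, 0.16 and 0.21, and the difference between stages had medians of 1.09 for the glutamatergic list (camera adjusted p = 0.0354, and 0.276 with an estimated correlation) and 0.39 for the motor neuron list (camera adjusted p = 0.461). The GABAergic list holds genes whose values had been seen, Dlx1 and Dlx2 among them. Over time the medians of the GABAergic, glutamatergic and motor neuron lists were 0.86, 1.74 and 2.47 in R42A and 3.80, 5.12 and 1.97 in MD.

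A hypothesis for the actin pattern is a change in the output of YAP and TEAD, transcription factors that respond to cell tension. The first list of 4 of their targets rose in ESC (3 up and 0 down, median 1.74, camera adjusted p = 0.00138, and 0.288 with an estimated correlation), fell in neural cells (0 up and 4 down, median -1.65, camera adjusted p = 0.00158, and 0.216 with an estimated correlation) and had a lower effect in neural cells (median -3.41, camera adjusted p = 5.89e-05, and 0.165 with an estimated correlation). The second list of 18 other targets had a median difference between stages of -0.63, with 7 of 18 lower (camera adjusted p = 0.00101, and 0.165 with an estimated correlation). In ESC 7 of 17 rose and 2 fell (camera adjusted p = 0.0597), and in neural cells 1 rose and 8 fell of 18 (camera adjusted p = 0.00844, and 0.216 with an estimated correlation). Over time the medians of the first and second list were 2.31 and 2.76 in R42A, and -0.81 and 1.57 in MD. Whether YAP and TEAD may drive the actin pattern stays open, since 11 of 18 targets did not pass. The list passed with the preset and not with the estimated correlation, which no list passed in any comparison. The lists of this part were not tested with clones left out.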
